A study of Drosophila melanogaster with 2 samples.

How the data were processed

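The libraries come from whole embryos of a fly strain with an eGFP-tagged CG9215, collected at 0 to 24 h, per the labels. Chromatin was sheared by sonication to a size range of 200 to 800, and the immunoprecipitation used an anti-GFP antibody, per the labels. The labels number the libraries as biological replicates 1 and 2, from different biosamples. The control library that the labels point to was not analysed here.

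The authors deposited 8 peak lists on the dm6 assembly. Each replicate has a ranked list and a thresholded list, and the series has 2 ranked lists, a thresholded list and a conservative thresholded list, per the text files deposited with them. The peak caller, the aligner and their versions are not given in the sources used here. All 3718 conservative peaks are found in the ranked list whose source peaks match the replicates, with 83694 of 100539 source peaks found in the list of replicate 1 and 88067 of 102852 in that of replicate 2. The conservative list is therefore read as the comparison of both replicates. No source peak of the other series-level ranked list was found in either replicate's list. The signal of a peak is the deposited value of the authors' peak caller, whose scaling is not stated. The score is a deposited whole number of at most 1000, computed by the authors from the irreproducible discovery rate (IDR), the expected share of peaks that do not recur. The ranked lists also hold the −log10 of the global IDR as deposited. All thresholded peaks have a score of at least 830, which corresponds to a −log10 IDR of at least 2, or an IDR of at most 0.01. Each list was filtered further: of the ranked peaks at that IDR, 185 are absent from the conservative list, 223 from the other series list, 217 from that of replicate 1 and 129 from that of replicate 2. The rule for this filter is not given in the sources used here.

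The signal was used only to rank peaks within a list and, on a log2 scale, to correlate the replicates. The files hold no read counts, so the depth of each library is unknown, and intervals below cover the sampling of peaks or genes only. Wilson 95% intervals are given for shares of peaks or genes. P-values across peaks or genes measure the spread over peaks or genes of this experiment, not over embryos.

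Gene models were taken from Ensembl release 115 (BDGP 6.54) and sequence from the RefSeq copy of Release 6, whose chromosome lengths contain every peak. Peaks on 2L, 2R, 3L, 3R, 4, X and Y were used for annotation and sequence. The 37 conservative peaks on unplaced scaffolds were left out, because scaffold names differ between the files and the reference. The annotation has 18277 genes on these chromosomes, 13968 of them protein coding, and 24111 start sites. A promoter peak has its summit within 500 bp of a start site. Features were assigned to summits in the order promoter, 5' UTR, 3' UTR, coding exon, non-coding exon, intron, intergenic, and compared with 100000 random positions on the same chromosomes.

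Replicate overlap counted thresholded peaks with at least 1 bp in common, with a one-sided permutation test of 1000 draws of as many peaks from the replicate's own ranked list. Promoter shares were tested against 1000 sets of random positions (two-sided permutation test) and against 113911 unselected peaks, which are peaks of the replicate-based ranked list that overlap no peak of any thresholded list (two-sided Fisher's exact test). Peaks per chromosome were tested with 10000 draws of start sites. Gene lists were tested with two-sided Fisher's exact tests against all other protein-coding genes, or all other genes for RNA gene lists, with Benjamini-Hochberg adjustment over the 30 lists. Of 1916 list entries, 1911 were found in the annotation. Older symbols were matched by RefSeq synonyms where these gave a single gene, and 10 by a table written by hand after the files were opened. Motifs, fixed as consensus patterns, were searched on both strands of 101 bp windows centred on summits and compared with unselected windows of the same promoter class, 1 per peak, by two-sided Fisher's exact tests adjusted over 15 motifs. Words of 8 bases with their reverse complements were tested one-sided on 2L and 2R, and the leading word was then tested on 3L, 3R, 4 and X. An adjusted p under 0.05 was called. For a comparison added after seeing the data, windows were matched on promoter class and on G+C content within 2 bases, which kept 3447 of 3681 peaks.

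The gene lists, motifs, tests and the rule for named genes were fixed before the data were examined. Named genes are those with a start site within 500 bp of the summit, or the nearest gene, for the 25 conservative peaks of highest signal; the 4 members with the strongest promoter peak in each list past the threshold and at most 2 in each other list; CG9215; and, for each replicate, the 5 strongest peaks that passed in that replicate alone and overlapped no conservative peak. The alternatives were reciprocal overlap of 50%, summits within 100 bp, the 500 peaks of highest signal, the other series list, the 1840 conservative peaks of highest signal, each replicate's own list in place of the conservative list, distances of 250 and 1000 bp, peak midpoints, genes with a ranked peak as background, genes off chromosome Y, 201 bp windows, windows 500 bp downstream, words of 6 and 7 bases and chromosome length as the expected share. Matching on G+C content and keeping 1 peak per overlapping region (3430 regions from 3681 peaks) were added after seeing the data.

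The tests were checked on simulated data. With 18277 genes and lists planted at a share of 50%, the gene list test called 59 of 60 planted and 1 of 540 unplanted lists. Simulated genes carried a peak independently at 1 rate. In the data a peak can count for several genes, and genes with several start sites have more chances, which these rates do not cover. The planted share was also above that of every called list, the highest being 46.2%. With an element planted in 3% of 3681 windows, the motif test called it in 20 of 20 runs and called 1 of 280 unplanted elements, and the word search placed it first in 5 of 5 runs. Both simulated sets were drawn from unselected windows and so shared their G+C content. The real sets differed, with a mean of 35.3% in conservative and 48.2% in unselected windows. The simulated rate of unplanted calls does not cover that difference. Random positions passed the promoter permutation test in 1 of 20 runs, and random start sites gave 1 call among 140 chromosome tests. Computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Biopython 1.88 and Matplotlib 3.10.9.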

Results

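Embryos of Drosophila melanogaster aged 0 to 24 h that carried a transgene for CG9215 fused to enhanced green fluorescent protein were studied by chromatin immunoprecipitation and sequencing with an antibody against the fluorescent tag. The labels give 1 group of 2 biological replicates and no other condition. The comparisons are therefore between the replicates, between the authors' peak lists, and of conservative peaks with random positions, genes or peaks outside the thresholded lists. CG9215 lies on chromosome X, and its longest annotated protein product has 560 residues with 6 matches to the C2H2 zinc finger pattern, a fold found in many DNA-binding proteins. The depth of each library is unknown, because the files hold peaks and no read counts. Coordinates are on the dm6 assembly, counted from 1.

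The strongest site of the tagged protein lay at velo, which encodes a SUMO protease, with a signal of 4174 in the conservative list, the list called across both replicates. Next came the promoters of CG14100 at 3639, of Ugalt, a UDP-galactose transporter, at 3447, and of aqz and lncRNA:CR43130 at 3258. The conservative list held 3718 peaks with a median width of 416 bp and a median signal of 146, against 4098 peaks in the other thresholded list of the series. Replicate 1 passed 3442 peaks and replicate 2 passed 2624. These came from 108069 and 112176 ranked peaks. The signal of each peak is the authors' own value and is used only to rank peaks within a list.

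Of the 25 conservative peaks of highest signal, 20 had their summit within 500 bp of a transcription start site, and all 25 overlapped a thresholded peak in each replicate. The velo peak spanned chromosome 3L positions 6747113 to 6747603, with its summit 95 bp from the start site. A further velo peak at 3L 6752120 to 6752589 had a signal of 2714. The CG14100 peak lay at 3L 19590408 to 19590820 and the Ugalt peak at X 2703672 to 2704091, 29 bp from the Ugalt start site. The peak at aqz and lncRNA:CR43130 lay at 3R 8820546 to 8821025, 1 bp from a start site. Other promoters in this set belonged to cyp33, a nuclear cyclophilin, at 3039, and to CG1648 and CG34033 at 3000. CG9630 had a signal of 2923, and the promoter of Cap-H2, a condensin II subunit, and MED7, a Mediator subunit, had 2901.

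Lower in the same set were the promoter of mRpL41 and lncRNA:CR44463 at 2897, that of kri and S6k, the ribosomal protein S6 kinase, at 2703, and that of the general transcription factor TfIIEalpha at 2623. The promoters of Nsun5 and CG42359 at 2586, of drk, an adaptor of receptor tyrosine kinases, and mars at 2484, and of CG5180 at 2383 followed. CG7601 and CIA30 shared a promoter peak of 2350, CHMP2B and Tcs5 of 2273, Shc and Atat of 2268, and Art3 and mRpS10 of 2075. CG5068 had 2248. The remaining 5 summits lay farther out. An Adf1 intron held a peak of 3119 at 2R 6662838 to 6663290, 793 bp from the start site, and a CG11050 intron held a peak of 2880 at 2L 6612474 to 6612912, 1019 bp away. The other intronic summits were at HmgZ with 2614, 557 bp away, and at Trl, which encodes GAGA factor, with 2220, 1487 bp from the nearest start sites of Trl and CG42507. The last, of 2258, lay in a non-coding exon of lncRNA:Vinr, 536 bp from the start site of lncRNA:CR44619.

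CG9215 itself was flanked by peaks. The gene spans X 15580930 to 15582874 on the minus strand. A peak at X 15582803 to 15583218 had its summit 137 bp upstream of the only annotated start site, with a signal of 227 and rank 1084 of 3718. A stronger peak at X 15579641 to 15579965, past the 3' end of the gene, had a signal of 903 and rank 126. Both sites passed in each replicate, with 532 and 92.5 in replicate 1 and 372 and 136 in replicate 2 for the downstream and the upstream site. The tagged transgene carries CG9215 sequence, so signal at this locus can come from the transgene.

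The replicates shared most of their strongest sites. Of the 3442 peaks of replicate 1, 2179 were overlapped by a peak of replicate 2, or 63.3% (95% Wilson interval 61.7 to 64.9). Of the 2624 peaks of replicate 2, 2234 were overlapped by a peak of replicate 1, or 85.1% (83.7 to 86.4). Random draws of as many ranked peaks were overlapped in 2.51% and 3.62% of cases on average. Both shares were above all 1000 draws in the one-sided permutation test, with p = 0.001, the smallest it can give. The draws were mostly weak peaks. The median signal was 13.4 and 13.9 in the ranked lists of replicates 1 and 2, against 85.4 and 92.9 in the thresholded lists. The test therefore shows that strong peaks recurred more than ranked peaks at large, whatever their origin. The median signal of peaks that were not shared was 58.4 in replicate 1, against 120 for shared peaks, and 59.3 in replicate 2, against 104. This difference was not tested.

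Signal was correlated between the replicates across 3674 conservative regions with a ranked peak in each. Spearman's rho was 0.81 and Pearson's r of log2 signal was 0.89. These values are across regions of 1 genome, which are not independent replicates. Regions entered the list because they ranked alike in both replicates, so the correlation is set in part by the list.

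**Figure D1:**
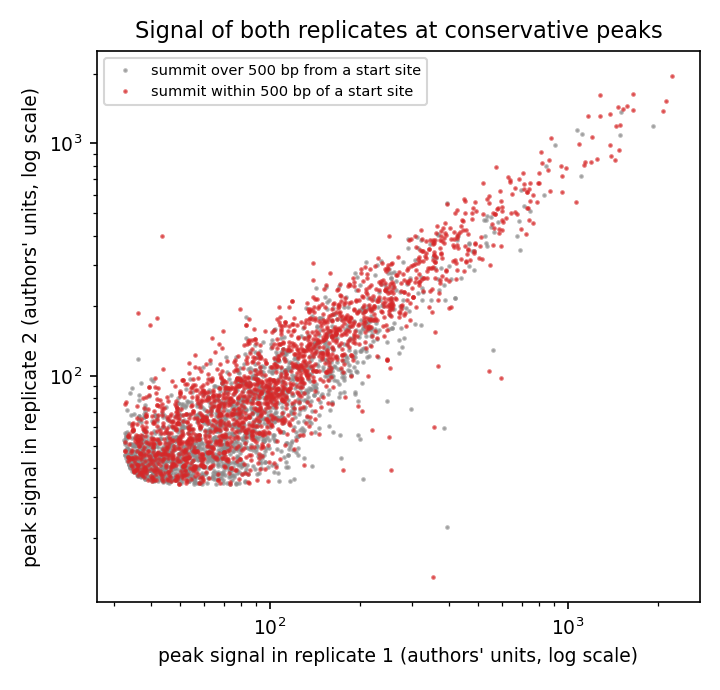
Signal of the ranked peak nearest each conservative summit in replicate 1 (x axis) and replicate 2 (y axis), in the authors' units on log scales, with 1 point for each of 3674 regions. Red points are summits within 500 bp of a start site and grey points are all others, and Spearman's rho over all points was 0.81.

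Some sites passed in a single replicate and overlapped no conservative peak, 538 in replicate 1 and 187 in replicate 2. The strongest of replicate 1 were at U2af50 and PIG-Q with a signal of 211, at 14-3-3zeta with 152, and in introns of rl with 142, of Dmtn with 142 and of CG9328 with 133. The Dmtn site also had a ranked peak in replicate 2, with a signal of 66.3, that did not pass there. The strongest of replicate 2 lay 655 bp from the start site of pan on chromosome 4, at 68490 to 68866, with a signal of 412. Next were the promoters of pum with 225, of wda and Pex11c with 218, of Msr-110 with 196, and of GPHR and CG11807 with 165. With 2 libraries, a site that passed in a single replicate cannot be tested for a difference.

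Peaks of the tagged protein were concentrated at promoters. Of 3681 conservative peaks on the assembled chromosomes, 1918 had a summit within 500 bp of an annotated start site, or 52.1% (95% Wilson interval 50.5 to 53.7). Random positions on the same chromosomes reached 13.6% ± 0.556 (SD over 1000 sets), and the two-sided permutation test gave p = 0.002, the smallest possible. Ranked peaks that overlapped no thresholded peak, here called unselected peaks, were at promoters in 13474 of 113911 cases, or 11.8%. Against these the odds ratio was 8.11 (95% interval 7.58 to 8.67, Fisher's exact test). Unselected peaks were not shown to be unbound, and 19.9% of them lay in coding exons, against 12.9% of random positions. Neither comparison set was matched for open chromatin, and no immunoprecipitation from untagged embryos was analysed here. Promoter signal that does not depend on the tag therefore stays open.

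The share at promoters was highest among the strongest peaks. Among the 369 peaks of highest signal, from 479 to 4174, 77.2% were at promoters. Among the 368 of lowest signal, up to 76.9, the share was 37.0%, and the lowest share, 33.2%, was among the 368 peaks ranked just above these. The group of lowest signal included 109 peaks with a signal under 20, of which 108 overlapped a stronger conservative peak. Its share is therefore not that of separate weak sites alone. No trend was tested. The median signal was 174 at promoters and 123 elsewhere. Summits away from promoters were mostly in introns, which held 1140 peaks or 31.0% of the list, against 39.9% of random positions. Intergenic summits made up 12.6% against 27.0% of random positions, and coding exons held 2.47% against 12.9%. In 3' UTRs the share was 0.625% against 5.19%, and in 5' UTRs over 500 bp from a start site it was 0.516% against 0.797%.

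Promoter summits lay on the upstream side of start sites. Of 1918 promoter summits, 1597 or 83.3% were upstream (95% Wilson interval 81.5 to 84.9), with a median position of -115 bp and quartiles of -195 and -43.3 bp. Unselected promoter peaks were upstream in 40.2% of cases and had a median position of 81 bp.

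**Figure D2:**
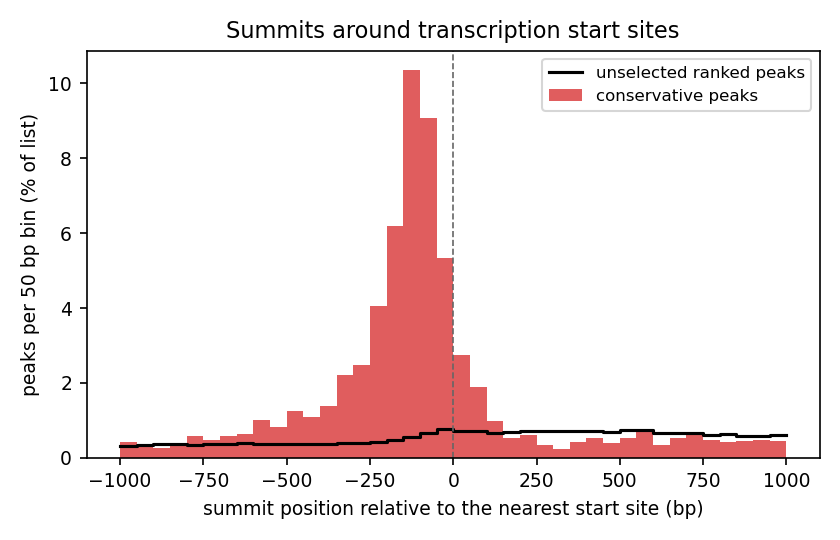
Position of summits relative to the nearest annotated start site (x axis, bp, negative values upstream) as the percentage of each list per 50 bp bin (y axis). Bars are conservative peaks, with the highest bin, from -150 to -100 bp, holding 10.4% of the list, and the black line is unselected ranked peaks, at 0.553% in that bin.

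Chromosome X held more peaks than its share of start sites and chromosome 4 almost none. X carried 753 peaks, or 20.5% of the list, against 16.4% of start sites, a ratio of 1.25. Chromosome 4 carried 1 peak, or 0.0272%, against 0.767% of start sites, and chromosome Y carried 3, or 0.0815%, against 0.469%. On 2R the ratio was 0.884, with 671 peaks. The permutation test of start sites gave an adjusted p of 0.0003 for each of X, 4, Y and 2R. The ratio on 3L was 1.07, with 754 peaks and an adjusted permutation p of 0.037, and this call was lost without replicate 1 (ratio 1.04, adjusted permutation p = 0.287) and without replicate 2 (1.05, 0.13), with adjusted p from 0.0031 to 0.948 over 6 alternatives. The ratio on 4 was 0.100 without replicate 1 and 0.077 without replicate 2, and that on Y was 0 and 0.315, all past the threshold. The ratio was 0.939 on 2L and 0.969 on 3R, neither past the threshold of the permutation test (adjusted p = 0.0635 and 0.275). With chromosome length as the expected share, neither 2R nor 3L passed, at ratios of 0.992 and 1.002. Unselected peaks were also almost absent from chromosome 4, with 12 of 113911. Of all unselected peaks, 17.7% were on X, 19.3% on 2R and 0.830% on Y. Conservative peaks were not tested against these shares.

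Genes of ribosomal, mitochondrial ribosomal, spliceosome and architectural proteins carried peaks more often than other genes. In all, 2574 of 18277 annotated genes had a conservative summit within 500 bp of a start site, and 2419 of these were protein coding. Of 93 ribosomal protein genes, 43 had one, or 46.2% against 17.1% of other protein-coding genes (odds ratio 4.17, 95% interval 2.77 to 6.27). Mitochondrial ribosomal protein genes had one in 25 of 73 cases, or 34.2% (odds ratio 2.53, 1.56 to 4.09), genes of the spliceosome and mRNA processing in 13 of 33, or 39.4% (3.16, 1.59 to 6.28), and genes of insulator and architectural proteins in 10 of 23, or 43.5% (3.72, 1.66 to 8.35). The adjusted p of Fisher's exact test was 9.2e-10, 0.00238, 0.00956 and 0.0114 in that order, over 30 lists fixed before the data were examined. Numbers of nearby start sites were not matched in these tests. Draws of genes matched in this way to ribosomal protein genes had a peak in 26.1% of cases. The other called lists had no such comparison.

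The ribosomal protein genes with the highest signal were RpL34b with 723, RpL32 with 499, RpS27 with 479 and RpS20 with 409. The highest signals at mitochondrial ribosomal protein genes were 2897 for mRpL41, 2075 for mRpS10, 1761 for mRpL23 and 1681 for mRpS23. Among the 1840 conservative peaks of highest signal alone, this list no longer passed (odds ratio 1.92, adjusted p of Fisher's exact test 0.134, from 0.000851 to 0.134 over 9 alternatives). In the spliceosome list, the splicing factor U2af38 had 467, SNRPG 466, SF2 324 and SC35 278. With start sites within 250 bp this list no longer passed (odds ratio 2.78, adjusted p of Fisher's exact test 0.0624, from 0.00151 to 0.0624 over 9 alternatives). In the architectural list, Chro, a chromosomal protein of interbands, had 1927, Trl had 1135, Cp190, an insulator cofactor, had 904, and row had 552. A peak can be near several genes, and another gene's start site was nearer the summit for 10 of the 43 ribosomal, 12 of the 25 mitochondrial ribosomal, 7 of the 13 spliceosome and 3 of the 10 architectural genes.

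Genes of tRNAs, microRNAs, small nucleolar RNAs and histones carried peaks less often than other genes. A start site here is the 5' end of an annotated transcript, whether or not transcription begins there. Numbers of start sites were not matched, so genes with several had more chances of a peak. Of 295 tRNA genes, 5 had a peak, or 1.69% against 14.3% of all other genes (odds ratio 0.114, 95% interval 0.0488 to 0.264). Of 260 microRNA genes 5 had one, or 1.92% (0.129, 0.0556 to 0.302), and of 257 small nucleolar RNA genes 8 had one, or 3.11% (0.205, 0.103 to 0.407). None of 111 replication-dependent histone genes had a peak, with an upper 95% Wilson bound of 3.35%. The adjusted p of Fisher's exact test was 4.2e-12, 2.3e-10, 2.4e-08 and 8.5e-09. Among genes with a ranked peak at a start site, only 1 histone gene was left and the histone call ended (adjusted p of Fisher's exact test 1, from 7.1e-10 to 1 over 9 alternatives). The histone share therefore cannot separate a lack of sites from a lack of ranked peaks at these genes. Its bound and p-value also count each histone gene as independent, which was not checked. The small nucleolar RNA list did not pass there either (odds ratio 0.494, adjusted p = 0.117), nor within 1000 bp (0.735, 0.186), by Fisher's exact test, with adjusted p from 4.9e-09 to 0.186 over 9 alternatives. The microRNA odds ratio was 0.043 without replicate 1, 0.0463 within 250 bp and 0.352 within 1000 bp, and that of tRNA genes was 0.215 within 1000 bp, all past the threshold. The strongest peaks near genes of these lists were 420 at tRNA:Tyr-GTA-1-8, 161 at tRNA:Phe-GAA-1-2, 142 at tRNA:Val-CAC-2-5 and 124 at tRNA:Trp-CCA-2-2. The small nucleolar RNA genes snoRNA:Psi28S-2949, snoRNA:Or-ACA6, snoRNA:Psi18S-920 and snoRNA:Me28S-A774b had 208, 208, 187 and 161. At mir-9377, mir-275, mir-2282 and mir-966 the signals were 399, 314, 109 and 87.7. Another gene's start site was nearer the summit for 4 of the 5 tRNA genes, 6 of the 8 small nucleolar RNA genes and 3 of the 5 microRNA genes. The summit near tRNA:Phe-GAA-1-2 was 78 bp from the RpL17 start site and 227 bp from its own, and that near snoRNA:Me28S-A774b was nearer to the RpS12 start site than to its own, 353 bp away. The summit near snoRNA:Psi18S-920, 476 bp away, was also 343 bp upstream of RpL10Ab and 233 bp from CG5946 and CG11597.

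Lists of patterning, differentiation and early embryonic genes did not pass the test. None of 8 Hox genes had a promoter peak. The share was 4 of 32 for anterior-posterior segmentation genes, with bcd at 241 and nkd at 220, and 1 of 32 for dorsal-ventral and mesoderm genes, with T48 at 120. It was 2 of 44 for neurogenesis and neuronal genes, elav at 1054 and brp at 120, 3 of 27 for muscle genes, with mbc at 439 and sls at 423, and 1 of 27 for genes of epidermis, trachea and cuticle, with trh at 145. Genes of endoderm, fat body and haemocytes had 2 of 27, bowl at 466 and Hnf4 at 232. Early zygotic genes had 3 of 25, with Sxl at 399 and dgrn at 156, and germline and maternal genes had 8 of 36, with tral at 458 and Sxl at 399. Small nuclear RNA genes had 1 of 32, snRNA:U5:35D at 173, where the summit was 150 bp from the ND-B17 start site and 454 bp from its own. Another gene's start site was also nearer the summit for mbc, 203 bp from its own and 59 bp from that of Nup98-96. The same held for tral, 181 bp from its own and 63 bp from that of sti. The lowest adjusted p of Fisher's exact test among these lists was 0.0769, for the neuronal list. Among genes with a ranked peak at a start site that list passed (odds ratio 0.199, adjusted p of Fisher's exact test 0.0127, from 0.0127 to 0.222 over 9 alternatives). Without replicate 1 the odds ratio went from 0.753 to 0.484 for segmentation genes, from 0.467 to 1.13 for endoderm, fat body and haemocytes, from 0.742 to 1.24 for early zygotic genes and from 0.29 to 0.619 for small nuclear RNA genes. Without replicate 2 it went from 0.281 to 1.04 for Hox genes and to 0.742 for endoderm, fat body and haemocytes, and none of these passed. The Hox ratio of 0.281 comes from no gene with a peak and so rests on the constant added to each count.

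Other gene lists held shares from 17.3% to 33.3% and did not pass. A peak counted for every gene with a start site within 500 bp. Of the genes named here, brm, RPA1, Rpn5, eIF6, GluProRS, ThrRS, ND-MWFE, ERR and S6k had another gene's start site nearer the summit. The RPA1 summit was 421 bp from its own start site and 98 bp from that of Mcm2. For the other genes named here, no other gene's start site was nearer. Polycomb and trithorax genes had a peak in 11 of 33 cases, with ph-p at 1940 and brm at 1367 (odds ratio 2.45, adjusted p of Fisher's exact test 0.0705). Genes of mitosis and cell cycle had 12 of 43, with CycA at 1375 and dap at 815, and DNA replication genes had 8 of 34, with RnrS at 485 and RPA1 at 314. Proteasome genes had 10 of 44, with Prosbeta2 at 317 and Rpn5 at 271, translation factors had 9 of 52, with eIF6 at 2019 and eIF3c at 563, and aminoacyl-tRNA synthetase genes had 8 of 33, with GluProRS and ThrRS both at 673. Oxidative phosphorylation genes had 16 of 92, with ND-MWFE at 581 and ND-ASHI at 513. Heat shock and chaperone genes had 8 of 31, with Hsp27 at 812 and Hsc70-5 at 441, and ecdysone and nuclear receptor genes had 6 of 26, with ERR at 667 and EcR at 477. Genes of Wnt, Notch, Hedgehog and EGF receptor signalling had 10 of 42, with drk at 2484 and spi at 679, and clock genes had 4 of 13, with sgg at 582 and Pdp1 at 289. Genes of the Hippo pathway and growth had 8 of 29, with S6k at 2703 and yki at 712, and this list passed within 1000 bp of start sites (odds ratio 3.33, adjusted p of Fisher's exact test 0.0114, from 0.0114 to 0.556 over 9 alternatives). Without replicate 1 the odds ratio of translation factors went from 1.04 to 1.64, and without replicate 2 that of aminoacyl-tRNA synthetases went from 1.59 to 1.003 and that of heat shock and chaperone genes from 1.73 to 0.85, none of them past the threshold.

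**Figure D3:**
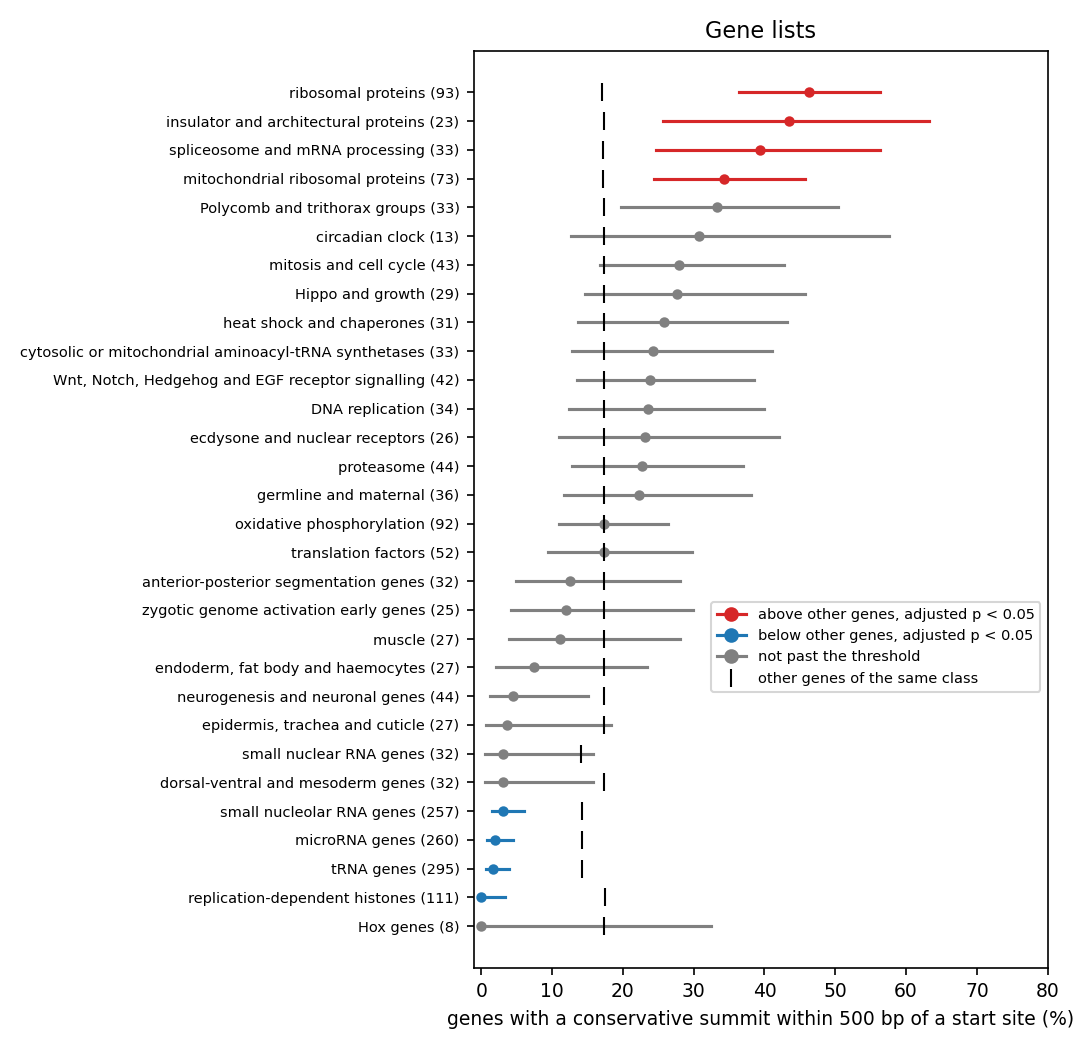
Percentage of each list's genes with a conservative summit within 500 bp of a start site (x axis), with 95% Wilson intervals as lines and the number of genes in parentheses. The lists' shares ran from 46.2% for ribosomal proteins to 0% for histone and Hox genes. Red lists were above and blue lists below other genes at an adjusted p under 0.05, and grey lists did not pass. Black ticks mark other genes of the same class.

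Sequence at conservative summits was poor in G and C. The median G+C content of the summit windows was 32.7% (quartiles 26.7 and 41.6), against 48.5% for unselected peaks and 42.6% for random positions. The 500 peaks of highest signal had a median of 28.7%. The low content was present at promoter summits, with a mean of 34.3%, and at the others, with a mean of 36.5%.

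**Figure D4:**
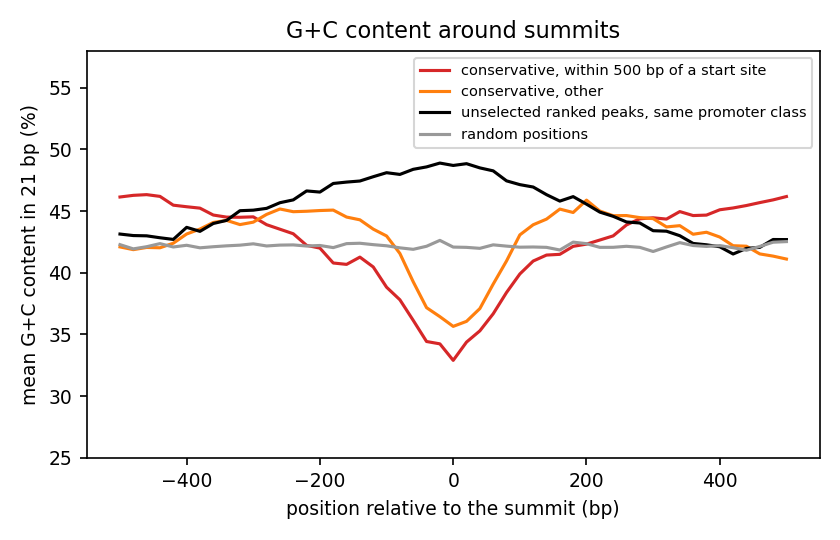
Mean G+C content in 21 bp windows (y axis, %) by position relative to the summit (x axis, bp) for 1918 promoter and 1763 other conservative summits, for unselected ranked peaks of the same promoter class and for random positions. Both conservative lines dip within about 100 bp of the summit, where unselected peaks are highest.

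The element of DREF, a factor of housekeeping promoters, was present in 63 of 3681 summit windows, or 1.71%, against 0.516% of matched unselected windows (odds ratio 3.3, 95% interval 1.98 to 5.49). The homeodomain core TAATTA was in 9.48% against 3.59% (2.81, 2.29 to 3.45), the TATA box in 1.96% against 0.978% (2.01, 1.34 to 2.99), Ohler motif 7, a core promoter element, in 2.31% against 1.41% (1.64, 1.16 to 2.32), and Ohler motif 6 in 7 windows against 0. Lower shares were found for the E-box CAGCTG, 3.59% against 6.3%, the Twist site, 3.37% against 4.67%, and the Pho site, 3.59% against 5.05%. With G+C content matched as well, none of these 3 passed (odds ratios 1.15, 0.983 and 1.05 in that order). The homeodomain core (0.872), the TATA box (0.764) and Ohler motif 6 (0.882) did not pass there either. In all, 8 of 15 motifs passed by Fisher's exact test, 5 higher and 3 lower, with adjusted p from 5.7e-24 for the homeodomain core to 0.0292 for Ohler motif 6. Ohler motif 6 passed under 2 of 7 alternatives, with odds ratios from 0.882 to 13.03, and did not pass without replicate 2 (odds ratio 2.15, adjusted p of Fisher's exact test 0.368, from 0.0124 to 1 over the alternatives). Ohler motif 7 did not pass among the 1840 peaks of highest signal (1.63, adjusted p of Fisher's exact test 0.156, from 4.3e-14 to 0.156). Against windows 500 bp downstream of the same summits, the TATA box (1.47) and the Pho site (0.858) did not pass, and the odds ratio was 5.6 for the DREF element, 4.25 for Ohler motif 7 and 1.71 for the homeodomain core.

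The other 7 motifs did not pass. M1BP's core promoter motif was in 16 windows against 6, the Zelda site in 20 against 22, the Su(Hw) site in 12 against 5, the GAGA element in 37 against 56, the Dorsal site in 8 against 19, the initiator in 282 against 332 and the CTCF core in 64 against 42. Without replicate 1 the M1BP motif (odds ratio 7.02) and the initiator (0.81) passed, and without replicate 2 the GAGA element (0.604) and the CTCF core (1.67) passed, with adjusted p of Fisher's exact test of 0.0218, 0.0467, 0.0474 and 0.0123. Of 7 alternatives, the M1BP motif passed under 4, with odds ratios from 1.22 to 15.1, the GAGA element under 4 (0.408 to 1.20), the CTCF core under 4 (1.21 to 2.59) and the initiator under 3 (0.776 to 0.890). Their adjusted p of Fisher's exact test ranged from 2.8e-05 to 1, from 8.9e-06 to 0.792, from 0.000473 to 0.523 and from 0.00315 to 0.232. The odds ratio of the Zelda site was 0.911, and 0.588 without replicate 1. The calls changed once windows were matched on G+C content as well, a comparison chosen after seeing the data. There the DREF element (odds ratio 1.85, 95% interval 1.2 to 2.84), Ohler motif 7 (2.17, 1.48 to 3.19) and the CTCF core (2.56, 1.61 to 4.06) passed, with adjusted p of Fisher's exact test of 0.0289, 0.000473 and 0.000473, and no other motif did. The odds ratio of the homeodomain core was then 0.872.

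Short words rich in A and T led the search for sequence at summits. On chromosomes 2L and 2R, 416 of 32305 words of 8 bases passed, and 381 of them had at most 1 G or C. The leading word was TAAAAATA. On the other chromosomes it was in 5.65% of windows against 1.09% (odds ratio 5.32, 95% interval 3.47 to 8.17, one-sided Fisher's exact p = 4.5e-19). Mean G+C content was 35.3% in conservative and 48.2% in unselected windows. The test therefore cannot separate this word from the low G+C content of the windows. With windows matched on G+C content, 0 of 31546 words passed Fisher's exact test after adjustment and 486 were under an unadjusted p of 0.05. The leading word was then AGCATTGC, found on the other chromosomes in 24 of 2202 windows against 3 of 2174 (odds ratio 6.98, 95% interval 2.27 to 21.4, one-sided Fisher's exact p = 2.7e-05).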

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

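No test was run on the counts here, which describe peaks that the comparisons did not use. The conservative list held 37 peaks on unplaced scaffolds, all of them scaffolds assigned to chromosome X, which the annotation and sequence comparisons did not use. The conservative list also lacked 185 ranked peaks whose IDR was at most 0.01, of which 127 lay on the assembled chromosomes and 58 on scaffolds. The strongest of these had a signal of 3820, above that of all but 1 peak in the list.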

How the results depend on the processing

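Comparisons with matched G+C content and with 1 peak per overlapping region were chosen after seeing the data. The overlap of replicates stayed above the permutation draws under reciprocal overlap, summit matching and the 500 strongest peaks, from 52.1% to 83% of replicate 1 peaks and from 69.4% to 83% of replicate 2 peaks. Promoter shares stayed above random positions under 8 alternatives, from 41.7% to 62.8%, and odds ratios against unselected peaks ranged from 5.99 to 12.6 under 6. Between 7 and 8 gene lists passed under 9 alternatives, and the ribosomal protein odds ratio ranged from 3.45 to 4.77. With summits within 100 bp, rho was 0.83. With chromosome length as the expected share, 3 chromosomes passed in place of 5. With matched G+C content, 3 motifs passed in place of 8, 2 of them shared, and among the 8 called motifs the odds ratio turned for Ohler motif 6 (0.882), the E-box (1.15), the TATA box (0.764), the Pho site (1.05) and the homeodomain core (0.872), none of them past the threshold. Motifs that were not called turned as well, without passing: the GAGA element (1.20 with matched G+C content, 1.10 in wider windows), the Zelda site (2.61 with matched G+C content, 1.196 with the other series list) and the Dorsal site (1.55 with matched G+C content). Matched G+C content left 0 words past the threshold in place of 416, with 486 of 31546 words at an unadjusted p of Fisher's exact test under 0.05. The count of words was 108 against windows 500 bp downstream, with the cause not tested, and 183 for the 1840 strongest peaks, which are fewer windows. The leading word of each alternative had an odds ratio from 2.61 to 6.98 on the other chromosomes. The leading word differed between alternatives, so this range does not test any 1 word. Among single results, calls were lost or turned under some alternative for 4 gene lists, 7 motifs and 2 chromosomes, and gained for 2 lists and 4 motifs. Values turned without passing for 7 lists that were not called and for 2 chromosomes. With the other series list these were translation factors (0.986), endoderm, fat body and haemocytes (1.10) and early zygotic genes (1.21). Translation factors were already level with other genes in the conservative list (17.31% against 17.32%). Their ratio of 1.04 there lay above 1 only through the constant added to each count. The proteasome turned among the 1840 strongest peaks (0.870), oxidative phosphorylation within 1000 bp (0.941) and chromosome 2L with length as the expected share (1.065). Leaving out each replicate in turn gave from 0.959 to 1.09 for oxidative phosphorylation, 0.347 to 1.04 for Hox genes, 0.742 to 1.13 for endoderm, fat body and haemocytes, 0.808 to 1.24 for early zygotic genes, 0.850 to 1.51 for heat shock and chaperones, and a ratio of 0.968 to 1.003 on 3R. Depth is unknown, so whether weaker sites were missed cannot be assessed.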

Other observations

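The tests of unselected and of distal G+C content, of unselected peaks on chromosome 4, of other housekeeping genes and of promoter shares of peaks shared or not shared between replicates were chosen after the result was seen. Promoter sites of the tagged protein often lay between genes transcribed away from each other, as at Cap-H2 and MED7 or Art3 and mRpS10. Of 1918 conservative promoter summits, 751 or 39.2% lay between divergent start sites (95% Wilson interval 37.0 to 41.4), against 3.9% (3.58 to 4.24) of unselected promoter peaks (odds ratio 15.9). Positions set at the summits' own distances from random start sites did so in 17.2% of cases on average and in at most 19.4% over 100 draws (permutation p = 0.01, the smallest possible), so the upstream position of summits alone gives a lower share. A preference of the tagged protein was not separated from other features of divergent promoters, such as housekeeping genes.

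Thresholded peaks that overlapped no thresholded peak of the other replicate were less often at promoters. In replicate 1, 61.9% of peaks shared with replicate 2 and 35.1% of the others were at promoters (odds ratio 3.01, 95% interval 2.60 to 3.48, Fisher's exact p = 2.1e-51). In replicate 2 the shares were 62.2% and 49.5% (odds ratio 1.68, 1.35 to 2.08, Fisher's exact p = 3.7e-06). Peaks that were not shared also had the lower median signal, 58.4 against 120 in replicate 1 and 59.3 against 104 in replicate 2, and signal was not held equal in this comparison. Of the 1263 such peaks of replicate 1, 538 overlapped no conservative peak, and of the 390 of replicate 2, 187 did not, so the others lie in the list called across replicates. Among conservative peaks, 109 had a signal under 20, and 108 of these overlapped a stronger conservative peak, with a median distance of 203 bp between summits.

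Low G+C content at conservative summits was weighed against technical explanations. A library bias towards fragments poor in G and C would also lower the G+C content of unselected peaks, but these were 4.96 percentage points above random positions over a wider window (95% interval 4.86 to 5.05). The position of promoters alone does not account for it either, since conservative summits away from start sites were lower than random positions away from start sites by a difference of -5.71 points (-6.28 to -5.14). Whether the tagged protein prefers such sequence or such sequence marks open chromatin was not tested, and the design gives no group that would separate these.

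The near-absence of chromosome 4 extended to peaks of every rank. Unselected peaks there numbered 12, a ratio of 0.0107 to the 1116 that its length would give, and the ranked lists held 17 peaks there in replicate 1 and 16 in replicate 2. The absence may therefore arise before peaks were ranked, in the reads, the control or a filter. The G+C content of chromosome 4, 35.2%, would still give 524 unselected peaks at the density of the other chromosomes, a ratio of 0.0229, so this content is not the whole cause. Whether a processing step removed peaks there or signal was lacking is open, and no biological explanation was tested.

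Peaks at ribosomal protein promoters could reflect strong transcription, which can raise immunoprecipitation signal whatever the protein. Strong transcription of housekeeping genes stays open, since transcription was not measured and the other housekeeping lists differed. Of these 6 lists, 4 had an odds ratio whose upper 95% bound reached the lower bound of ribosomal protein genes (2.77). Over the alternatives from 4 to 6 did. Translation factors went from 1.04 to 1.64 without replicate 1 and 1.44 without replicate 2. Their upper bounds reached the ribosomal bounds of those settings, 2.62 and 2.30. A small list has a wide interval and can reach the bound without resembling ribosomal protein genes. The proteasome (odds ratio 1.45, 0.728 to 2.91) and aminoacyl-tRNA synthetases (1.59, 0.732 to 3.47) reached it and were not called. The mitochondrial ribosomal and spliceosome lists reached it and were called. Crowding of start sites alone does not account for the share, since random protein-coding genes with as many start sites nearby had a peak in 26.1% of cases (18.3 to 34.4 in 95% of 10000 draws), against 46.2% (permutation p = 0.0001, the smallest possible). An immunoprecipitation from untagged embryos was not analysed here, so signal that does not depend on the tag stays open, and no biological explanation was tested.

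Peaks on chromosome X were searched for the word GAGAGAG, since GA-rich elements recruit dosage compensation in flies. The word was in 17 of 753 windows on X, or 2.26%, against 0.684% on the autosomes (odds ratio 3.37, 95% interval 1.77 to 6.41, Fisher's exact p = 0.000607), and among unselected windows in 1.43% against 1.23% (odds ratio 1.16). The word may mark a small part of the sites on X, and other GA-rich sequence was not tested.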
